A study of Homo sapiens with 24 samples.

How the data were processed

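The series measured RNA in HEK293T cells, a human embryonic kidney line, that carried 1 of 3 proteins fused to miniSOG. TIA1 and G3BP2 are proteins of stress granules, and DDX6 is an RNA helicase of processing bodies (P-bodies). In blue light miniSOG makes singlet oxygen, which oxidises guanines nearby, and propargylamine then reacts with the oxidised bases, so that labelled RNA can be joined to biotin by click chemistry and captured on streptavidin. The labels give propargylamine at 10 mM for 5 min and light at 24 mW/cm2 for 15 min. Sodium arsenite was used at 0.5 mM, for 40 min before the probe and for 1 hr in all, and the DDX6 cells were also labelled without it.

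Each of the 4 combinations of cells and treatment had 3 kinds of library. Labelled captures hold the RNA eluted from streptavidin, inputs hold the same labelled RNA before capture, and no-probe captures went through the capture without propargylamine and show what binds without label. With 2 replicates each, this made 24 libraries in 12 groups. Groups were taken from the labels of the samples and were settled before the data were examined, as were the comparisons, their tests, the gene lists, the rule for named genes and the alternatives, apart from those called added later below.

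The deposited table gives raw counts per Ensembl gene, from Ensembl release 87 per the file headers, as whole numbers with each replicate in its own column. Per the labels, the authors trimmed reads with cutadapt 1.18, checked them with FastQC 0.11.8, aligned them with HISAT2 2.1.0 and counted them with HTSeq 0.7.2, with SAMtools between, against GRCh38. The strand setting and the handling of reads with several places are not stated, and the labels name a library kit that does not keep the strand. Counts of antisense and overlapping genes, of pseudogenes and of near-identical copies (5S rRNA, 7SL, U snRNA and histone genes) are therefore uncertain.

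Of 57992 genes in the table, 57388 matched GENCODE release 29, which gave symbols, gene types, positions, exon lengths and GC content, and 39646 had at least 1 count in some library. Exon length and GC content are those of the longest annotated transcript of each gene, which need not be the one present in these cells. Total counts per library ran from 1129510 to 5919467, and the labelled captures, from 3344960 counts up, were the deepest group on average. Depth sets the counting error of a gene, and since the reads carry no molecular identifiers, counting error is a lower limit of the real error.

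Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts were kept by filterByExpr, which left 14360 tested genes, and libraries were scaled by the trimmed mean of M values (TMM). A single quasi-likelihood model with 1 coefficient for each of the 12 groups was fitted to the 24 libraries, with 12 residual degrees of freedom and a common biological coefficient of variation of 12.9%. Contrasts were tested with edgeR's quasi-likelihood F-test, two-sided, and p-values were adjusted over the 14360 genes by the Benjamini-Hochberg method, with 0.05 as the threshold. Levels are given as TMM-normalised CPM (counts scaled to a common library size), as mean and SD of 2 libraries. Fold changes are on the log2 scale, as estimate ± SE of the model. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between samples as labelled, with 2 per group.

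Enrichment is a labelled capture over its input, and probe dependence is a labelled capture over its no-probe capture. A gene higher in both comparisons was counted as enriched in both. The no-probe capture over input was computed in the same model and is called background. Differences between baits under arsenite, and between arsenite and no arsenite for DDX6, were tested as differences of the enrichments (interaction terms), and arsenite was also compared with no arsenite in the DDX6 inputs. Each bait has its own cell line, so bait and line cannot be separated by the design. Replicate numbers were treated as unpaired.

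Gene lists were tested with camera of limma 3.58.1, with the preset correlation of 0.01 between genes, for the 24 lists with at least 5 tested genes, adjusted by the Benjamini-Hochberg method within each comparison. Of 312 such tests 180 passed, and 21 of them also passed with the correlation estimated from the libraries. With 12 residual degrees of freedom the estimated correlations are themselves uncertain. In 19 of the 312 tests the median, the mean and the direction of the test differed in sign, with a median of at most 0.27 in size, and none of those passed. For lists, the count of genes past the threshold over all genes is given, and the count adjusted over the list alone beside it. Members of lists too small for camera are given gene by gene. GC content was not held in any list test.

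Named genes were chosen by rule. For each comparison of enrichments, of differences and of arsenite, they are the 6 with the largest positive and the 4 with the largest negative change among genes past the threshold with a mean of at least 10 CPM, with libraries of the groups not overlapping where 2 groups were compared. For enrichment, positive genes also had to be higher than in the no-probe captures. The highest, lowest and median member of each list and a fixed set (TIA1, G3BP2, DDX6, AHNAK, NORAD, DYNC1H1, GAPDH, HSPA1A, HSPA1B, HMOX1, MALAT1 and RN7SL1) were added. HSPA1A, HSPA1B and RN7SL1 were not among the tested genes. An antisense RNA on the X chromosome that the rule picked in the arsenite comparison of inputs was left out, because its reads cannot be told from those of its partner.

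GC content and exon length were compared with enrichment by Spearman correlation across 12339 protein-coding genes with both values. Such correlations run across genes, which are not independent replicates. The overlap of gene sets was compared with the number expected for independent sets and with 20 simulated data sets without any difference between groups. In simulated data with 100 genes changed 4-fold, 77 were found for an enrichment, 74 for a difference of enrichments and 88 for a comparison of inputs. For 2-fold changes these numbers were 59, 21 and 44, and at most 13 of 14120 unchanged genes were called. Nearly all simulated genes were unchanged, unlike in the real enrichments, so the shares found there can differ.

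Alternatives were DESeq2 size factors in edgeR, total counts without TMM, scaling without genes of the mitochondrial genome and rRNA genes, no filter on low counts, a filter at 50 counts, the Wald test of DESeq2 1.42.0, a fit to only the libraries compared, replicate number as a block, a further threshold of 1 on the log2 scale, list medians after a loess trend with exon length was removed, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. The no-probe captures in place of the inputs as reference for the differences of enrichment were added later. The length trend was fitted to all tested genes, small RNAs included. For lists of short RNAs or short mRNAs, medians after its removal therefore do not separate length from class of RNA. Under total counts, the median log2 fold change of all genes moves from near 0 to 0.675, 0.522, 0.513 and 0.466 for enrichment with TIA1, G3BP2, DDX6 under arsenite and DDX6 without it. Changes are relative to the bulk of the genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main analysis.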

Results

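RNA was measured by sequencing in HEK293T cells with TIA1-miniSOG, G3BP2-miniSOG or miniSOG-DDX6, as labelled capture, input and no-probe capture, with 2 libraries per group and 1129510 to 5919467 counts per library. All 3 lines were labelled under arsenite, a poison that stalls translation and makes cells form stress granules, and the DDX6 line also without it. Replicates correlated with r between 0.926 and 0.989 on log2 CPM across genes. The lowest correlation was that of the no-probe captures with G3BP2, and the no-probe captures of the DDX6 cells under arsenite differed most in their shares of the mitochondrial genome, 21.44% and 27.96%.

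The genes of the baits were examined first, as a check of the labels. TIA1 stood at 357 ± 0.811 CPM (SD, n = 2) in the input of its own line, which was 5.89-fold its level in the G3BP2 line and 5.97-fold that in the DDX6 line. G3BP2 stood at 456 ± 17.0 CPM in the input of its line, 2.45-fold the level in the DDX6 line. DDX6 stood at 1110 ± 16.8 and 1130 ± 36.1 CPM in the inputs of its line with and without arsenite, against 178 CPM in the TIA1 line. Each bait gene was higher in its own line (adjusted p between 1.19e-10 and 4.92e-05 for TIA1 and G3BP2, and 1.61e-10 and 1.8e-11 for DDX6, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as throughout). The inputs of the lines also differed in other genes, with 594 past the threshold between TIA1 and G3BP2, 126 between TIA1 and DDX6, and 113 between G3BP2 and DDX6.

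Capture of labelled RNA changed what kind of RNA was sequenced. Reads of the mitochondrial genome fell from 31.36% ± 0.396 of counts in the TIA1 input to 7.54% ± 1.329 in the labelled capture (SD, n = 2), while the no-probe capture held 29.02% ± 1.711. The same shares were 24.065%, 1.79% and 20.22% for G3BP2, 29.68%, 3.375% and 24.7% for DDX6 under arsenite, and 28.69%, 3.865% and 21.19% for DDX6 without arsenite. Nuclear protein-coding genes rose in turn, from between 49.33% and 53.61% of counts in the inputs to between 82.595% and 91.42% in the labelled captures, with 44.265% to 60.285% in the no-probe captures. These shares are described without a test.

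**Figure D1:**
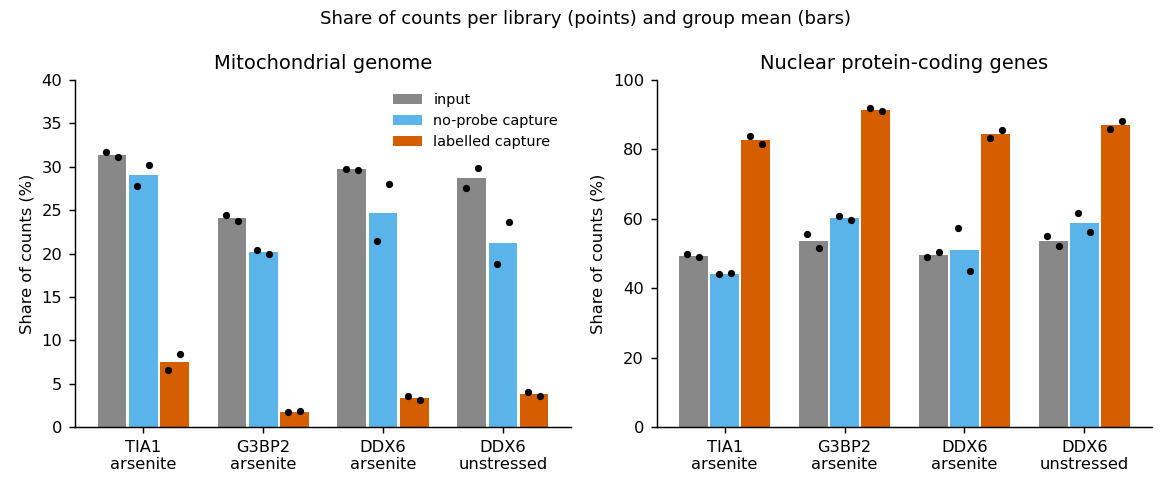
Share of counts (%) from the mitochondrial genome (left) and from nuclear protein-coding genes (right), for input, no-probe capture and labelled capture in each combination of cells and treatment; bars are means and points are the 2 libraries. In the labelled captures the mitochondrial share averaged 7.54% or below in each group. Group averages were at least 20.22% in the no-probe captures and 24.065% in the inputs.

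With TIA1 under arsenite, the labelled capture compared with its input asks which RNAs lie near this stress granule protein. Total counts per library ranged from 4219278 to 5138758 in the capture and from 2511043 to 2685287 in the input. POLR2M rose 5.84-fold (2.55 ± 0.27 on the log2 scale, 66.8 against 11.2 CPM, adjusted p = 2.5e-08, n = 2 against 2). DCK, the kinase that salvages deoxycytidine, rose 4.8-fold (2.26 ± 0.23) and TSNAX, the partner of translin, 4.73-fold (2.24 ± 0.20). Background changes of these genes were -0.18, -0.37 and -0.13. NORAD, a long noncoding RNA that binds Pumilio proteins and is known in stress granules, rose 3.4-fold (1.76 ± 0.21, 421 ± 56.0 against 124 ± 5.97 CPM, adjusted p = 1.49e-07). MALAT1, an abundant RNA of nuclear speckles, rose 1.91-fold (0.93 ± 0.22, 3390 ± 895 against 1780 ± 333 CPM, adjusted p = 0.00117), but not without replicate 1 of the TIA1 labelled capture (adjusted p = 0.0583). In all, 2789 genes were higher and 2349 lower, but 1070 and 1119 with a further threshold of 1 on the log2 scale.

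RNAs of mitochondria and small noncoding RNAs fell in the TIA1 capture. All 13 mitochondrial mRNAs were lower, with a median of -2.36 against 0.21 for background, and the list test passed (adjusted p = 2.88e-29, and 0.0284 with an estimated correlation). MT-ND2, a subunit of respiratory complex I, fell by 2.36 ± 0.23, and the mitochondrial rRNAs MT-RNR1 and MT-RNR2 fell by 2.69 and 2.83. Of 75 snoRNAs and scaRNAs, guides of RNA modification, 63 were lower over all genes and 69 adjusted over the list alone, with a median of -2.80 (adjusted p = 8.11e-33, and 0.0756 with an estimated correlation). SNORD89 fell by 4.32 ± 0.55, from 41 and 46 counts in the inputs to 7 and 5. Lower were also 14 of 24 spliceosomal snRNAs (median -2.57, 14 adjusted over the list alone, adjusted p = 1.14e-09, and 0.159 with an estimated correlation), with RNU4-2 at -3.22 ± 0.43. All 8 cytoplasmic small RNAs were lower (median -3.21, 8 adjusted over the list alone, adjusted p = 0.0756 with an estimated correlation), among them RNY3 at -3.78 ± 0.46 and the signal recognition particle RNA RN7SL2 at -2.39 ± 0.30. With a trend with exon length removed, the medians of these 3 lists were -0.90, -0.51 and -1.16. The trend was fitted to all tested genes, these lists included, so length and class were not separated for such short RNAs.

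Several lists of mRNAs were lower with TIA1 as well. Of 80 ribosomal protein mRNAs 71 were lower and 1 higher over all genes, and 74 and 1 adjusted over the list alone, with a median of -1.26 and a background of 0.07 (adjusted p = 2.31e-46, and 0.0756 with an estimated correlation). RPS27 fell by 2.28 ± 0.24. Histone mRNAs were lower for 41 of 48 (46 adjusted over the list alone, median -1.43, and -0.65 after a trend with exon length was removed, adjusted p = 0.131 with an estimated correlation). Those of oxidative phosphorylation were lower for 56 of 72 with 1 higher (59 and 1 adjusted over the list alone, median -1.11, and -0.71 after that trend was removed, adjusted p = 0.0756 with an estimated correlation), and glycolysis mRNAs for 11 of 17 with 1 higher (12 and 1 adjusted over the list alone, median -0.67, adjusted p = 0.178 with an estimated correlation). COX6B1 fell by 2.11 ± 0.26, GAPDH by 1.50 ± 0.20, and FTL, the ferritin light chain, by 2.16 ± 0.22. Among lists that passed camera, the medians below 0 that changed sign under total counts were those of translation factors (2 of 19 higher and 10 lower, -0.43, adjusted p = 0.116 with an estimated correlation) and 2 more lists. These were snoRNA host genes (15 of 26 lower, -0.60 against 0.06 under total counts, adjusted p = 0.0756 with an estimated correlation) and cytoskeleton (9 of 17 lower, -0.61 against 0.05, and -0.27 after the length trend was removed, adjusted p = 0.174 with an estimated correlation).

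Higher with TIA1 were mRNAs of cell division, P-body proteins and zinc finger proteins. Of 41 genes of mitosis and the centrosome 21 were higher and 1 lower (22 and 1 adjusted over the list alone), with a median of 0.47 and a background of -0.14 (adjusted p = 0.000325, and 0.207 with an estimated correlation). TOP2A, the topoisomerase of mitotic chromosomes, rose by 1.11 ± 0.19. Of 41 P-body genes 19 were higher and 2 lower (21 and 2 adjusted over the list alone, median 0.37, adjusted p = 6.69e-05, and 0.0756 with an estimated correlation), with CPEB2, a regulator of translation, at 2.08 ± 0.43 and CNOT3, a part of the deadenylase complex, at -1.43 ± 0.37. Zinc finger genes split into 93 higher and 30 lower of 378 (92 and 30 adjusted over the list alone, median 0.35, and 0.19 after a trend with exon length was removed, adjusted p = 0.0112, and 0.0881 with an estimated correlation), from ZNF772 at 1.89 ± 0.37 to ZNF581 at -1.41 ± 0.26. The stress granule marker transcripts were higher for 3 of 6 tested (3 adjusted over the list alone, median 0.48, and 0.19 after that trend was removed, adjusted p = 0.0112, and 0.191 with an estimated correlation). AHNAK at 0.30 ± 0.30 (adjusted p = 0.468) and DYNC1H1 at 0.16 ± 0.19 (adjusted p = 0.534) did not pass. Genes of stress granule proteins went both ways, with 7 of 30 higher and 5 lower (adjusted p = 0.691), from G3BP1 at 1.25 ± 0.20 to YBX1 at -1.41 ± 0.21.

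Stress response genes did not pass as lists in the TIA1 capture. Among 18 targets of NRF2, the regulator of the oxidative stress response, 4 were higher and 8 lower (adjusted p = 0.104), with GCLC, which makes glutathione, at 1.52 ± 0.20. Immediate early genes were higher for 6 and lower for 5 of 32 (adjusted p = 0.935), with MYC at 1.31 ± 0.19 and EGR1 at -0.99 ± 0.21. Heat shock genes (2 higher, 4 lower of 18, adjusted p = 0.829), ATF4 targets (4 and 6 of 26, adjusted p = 0.479), and chaperones of the endoplasmic reticulum (6 and 10 of 27, adjusted p = 0.0941) did not pass either. The same held for chromatin regulators (18 and 4 of 51, adjusted p = 0.128), giant ubiquitin ligases (4 and 1 of 15, adjusted p = 0.36) and very long cytoskeletal genes (6 and 9 of 40, adjusted p = 0.935). Of 3 metallothionein and zinc export genes 1 was higher and 1 lower, and none of 3 tested markers of other cell types changed. The count of genes past the threshold, 5138, was 3267 without replicate 1 of the TIA1 labelled capture and 3311 without replicate 2 of the TIA1 input.

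**Figure D2:**
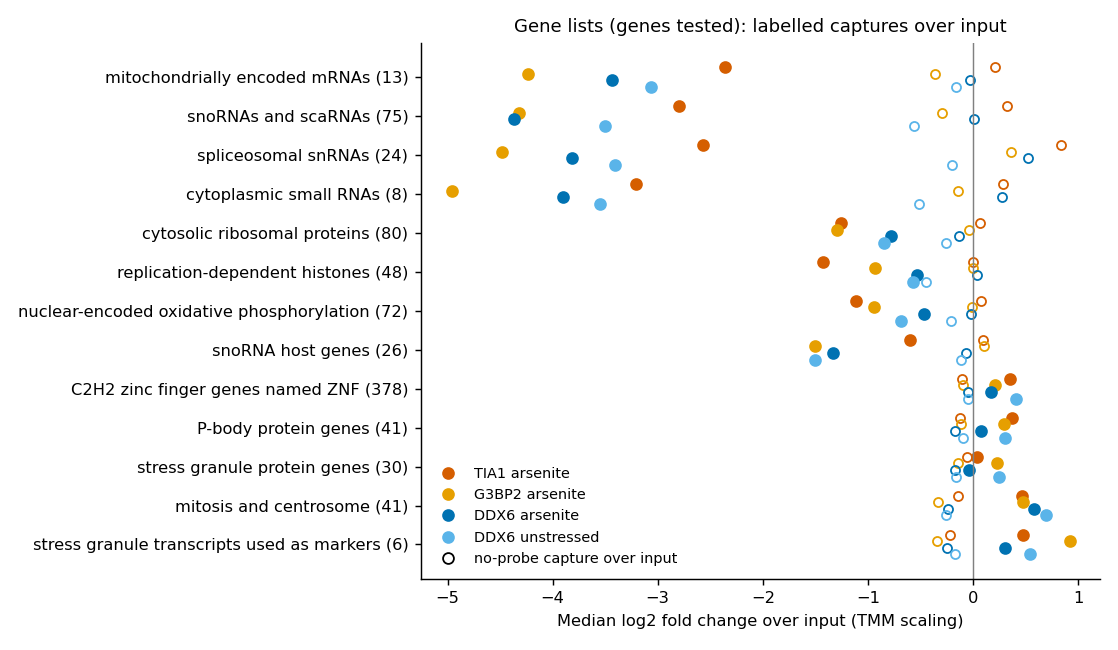
Median log2 fold change of labelled capture over input for 13 gene lists (number of tested genes in brackets) in the 4 combinations of cells and treatment (filled points), with the no-probe capture over input (open points). Mitochondrial mRNAs lay between -4.24 and -2.36 with background medians from -0.36 to 0.21, and mitosis genes between 0.47 and 0.70. Among plotted lists that passed camera, the snoRNA host genes with TIA1 (-0.60) and the histone and oxidative phosphorylation genes with DDX6 under arsenite (-0.53 and -0.47) changed sign under total counts.

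With G3BP2 under arsenite, the same comparison gave 2986 genes higher and 2509 lower than in the input, but 991 and 1552 with the further threshold of 1. ERLEC1, a lectin of the endoplasmic reticulum, rose 5.26-fold (2.39 ± 0.24, 71.5 ± 10.1 against 13.6 ± 0.493 CPM, adjusted p = 4.43e-09, n = 2 against 2). TDG, a DNA repair glycosylase, rose 4.31-fold (2.11 ± 0.20), DCK 4.09-fold (2.03 ± 0.22) and MSH6, a mismatch repair protein, 3.75-fold (1.91 ± 0.16), with background changes of -0.63 for TDG, 0.14 for DCK and -0.49 for MSH6. NORAD rose by 1.22 ± 0.20 and DYNC1H1, the dynein heavy chain, by 1.05 ± 0.19 (adjusted p = 6.26e-05). Of 6 tested stress granule marker transcripts 4 were higher (5 adjusted over the list alone, median 0.92, adjusted p = 0.00812, and 0.22 with an estimated correlation). AHNAK at 0.76 ± 0.31 missed the threshold (adjusted p = 0.0521). Nuclear RNAs fell, with MALAT1 at -1.85 ± 0.22 (adjusted p = 1.56e-07), NEAT1, the scaffold of paraspeckles, at -1.86 ± 0.26 and KCNQ1OT1, an imprinted antisense RNA, at -2.23 ± 0.17.

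Mitochondrial and small RNAs fell with G3BP2 as well, and its differences from TIA1 are tested further on. The 13 mitochondrial mRNAs had a median of -4.24 and a background of -0.36, and all were lower (adjusted p = 4.46e-61, and 0.00136 with an estimated correlation). MT-CO3, a subunit of cytochrome oxidase, fell by 4.24 ± 0.26, from 2100 ± 19.4 to 111 ± 9.16 CPM. Lower were 74 of 75 snoRNAs and scaRNAs (74 adjusted over the list alone, median -4.32, adjusted p = 1.24e-52, and 0.0254 with an estimated correlation). The same was true of 20 of 24 snRNAs (20 adjusted over the list alone, median -4.48, adjusted p = 0.0528 with an estimated correlation) and all 8 cytoplasmic small RNAs (median -4.96, adjusted p = 0.0506 with an estimated correlation). RNU5A-1 fell from 1020 ± 14.1 to 9.89 ± 1.83 CPM (-6.70 ± 0.55), where the no-probe capture was already lower than the input (background -1.53). The snoRNA host genes were lower for 20 of 26 (22 adjusted over the list alone, median -1.50, background 0.11, adjusted p = 7.86e-13, and 0.00733 with an estimated correlation), with ZFAS1 at -2.56 ± 0.34. Removing a trend with exon length brought the medians to -1.21 for snoRNAs and scaRNAs, -1.16 for snRNAs, -1.32 for cytoplasmic small RNAs and -0.85 for the host genes.

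Among mRNAs with G3BP2, 74 of 80 ribosomal protein genes were lower and 1 higher (76 and 1 adjusted over the list alone, median -1.29, adjusted p = 6.45e-41, and 0.104 with an estimated correlation). Lower too were 34 of 48 histones (35 adjusted over the list alone, median -0.93, but 0.15 after a trend with exon length was removed, adjusted p = 0.314 with an estimated correlation) and 50 of 72 genes of oxidative phosphorylation (52 adjusted over the list alone, median -0.94, and -0.34 after that trend was removed, adjusted p = 0.121 with an estimated correlation). Mitosis genes were higher for 23 of 41 and lower for none (27 and 1 adjusted over the list alone, median 0.48, background -0.33, adjusted p = 1.25e-06, and 0.162 with an estimated correlation), with TOP2A at 1.50 ± 0.19. Chromatin regulators were higher for 18 and lower for 5 of 51 (median 0.13, and 0.01 after that trend was removed, adjusted p = 0.0383, and 0.539 with an estimated correlation), from KDM5B, a histone demethylase, at 1.39 ± 0.18 to CHD2, a remodeller, at -0.93 ± 0.16. Immediate early genes were lower for 11 and higher for 4 of 32, with a median of -0.34 that became 0.20 under total counts and -0.20 after the length trend was removed (adjusted p = 0.0383, and 0.314 with an estimated correlation), from MYC at 1.02 ± 0.19 to FOSB at -2.31 ± 0.27. The cytoskeleton list was lower for 7 of 17, with a median of -0.47 that became 0.07 under total counts and -0.01 after the length trend was removed (adjusted p = 0.00523, and 0.314 with an estimated correlation). FTL fell by 2.41 ± 0.22 and GAPDH by 1.35 ± 0.20, while HSP90AA1, an abundant chaperone, rose by 1.00 ± 0.29 and DCP2, the decapping enzyme of P-bodies, by 1.53 ± 0.19. Zinc finger genes (69 higher, 14 lower of 378, adjusted p = 0.061), P-body genes (11 and 4 of 41, adjusted p = 0.0666) and stress granule protein genes (11 and 5 of 30, adjusted p = 0.217) did not pass as lists. Without replicate 1 of the G3BP2 labelled capture, 3633 genes passed the threshold in place of 5495.

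With DDX6 under arsenite, the capture asks which RNAs lie near this P-body helicase in stressed cells, and 2935 genes were higher and 2485 lower than in the input. These were 839 and 1481 with the further threshold of 1, and 1342 and 1358 in a fit to these libraries alone. TTC33 rose 3.82-fold (1.93 ± 0.25, 42.6 ± 0.0858 against 11.1 ± 0.443 CPM, adjusted p = 8.2e-07, n = 2 against 2, background 0.46), FZD6, a Wnt receptor, 3.79-fold (1.92 ± 0.25) and DCK 3.58-fold (1.84 ± 0.22). RPL22L1, a paralog of the ribosomal protein RPL22, rose 3.2-fold (1.68 ± 0.16, 154 ± 12.7 against 48.0 ± 4.27 CPM, adjusted p = 4.03e-09). Of 80 ribosomal protein genes 53 were lower (3 higher; 4 higher and 56 lower adjusted over the list alone, median -0.78, and -0.42 after a trend with exon length was removed, adjusted p = 0.584 with an estimated correlation). The mRNA of DDX6, to which the fusion gene adds, rose by 1.70 ± 0.19, that of G3BP2 by 1.34 ± 0.18, and ID2, an inhibitor of differentiation factors, by 1.33 ± 0.18. NORAD rose by 0.88 ± 0.20 (adjusted p = 0.001), but not without replicate 1 of the DDX6 arsenite labelled capture (adjusted p = 0.0552). MALAT1 and NEAT1 fell, by 2.00 ± 0.23 and 2.05 ± 0.28.

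Mitochondrial and small RNAs were lower in this capture too, and the differences between baits are tested further on. All 13 mitochondrial mRNAs were lower (median -3.44, background -0.03, adjusted p = 0.00269 with an estimated correlation), and so were 73 of 75 snoRNAs and scaRNAs (75 adjusted over the list alone, median -4.37, adjusted p = 0.0335 with an estimated correlation). Further lower RNAs were 15 of 24 snRNAs (16 adjusted over the list alone, median -3.82, adjusted p = 0.0705 with an estimated correlation), all 8 cytoplasmic small RNAs (median -3.90, adjusted p = 0.0625 with an estimated correlation) and 21 of 26 snoRNA host genes (23 adjusted over the list alone, median -1.33, adjusted p = 0.00883 with an estimated correlation). After removal of a trend with exon length these medians were -1.60, -0.86, -1.15 and -0.83, in the order from snoRNAs to host genes. RNU4-1 fell from 1270 ± 469 to 10.9 ± 3.56 CPM (-6.83 ± 0.55). Mitosis genes were higher for 25 and lower for 4 of 41 (27 and 4 adjusted over the list alone, median 0.58, adjusted p = 6.22e-06, and 0.252 with an estimated correlation), from TOP2A at 1.48 ± 0.19 to PCNT, a scaffold of the centrosome, at -1.11 ± 0.17. Histone genes were lower for 17 and higher for 2 of 48 (median -0.53, but 0.53 after a trend with exon length was removed, adjusted p = 0.812 with an estimated correlation). Genes of oxidative phosphorylation were lower for 32 and higher for 3 of 72 (median -0.47, and -0.03 after that trend was removed, adjusted p = 0.67 with an estimated correlation). Both lists had medians above 0 under total counts (0.01 and 0.07). The length trend was fitted with the small RNAs, while among protein-coding genes alone enrichment had a rho of 0.143 with exon length. The medians without the trend therefore do not tell whether mRNA length accounts for the fall of these 2 lists. Stress granule marker transcripts (2 higher and none lower of 6, adjusted p = 0.236), P-body genes (12 higher, 6 lower of 41, adjusted p = 0.29), stress granule protein genes (9 and 8 of 30, adjusted p = 0.742), chromatin regulators (8 and 19 of 51, adjusted p = 0.186), zinc finger genes (61 and 33 of 378, adjusted p = 0.29) and immediate early genes (7 and 8 of 32, adjusted p = 0.236) did not pass as lists. KMT2D, a histone methyltransferase, fell by 1.60 ± 0.18 and FOSB by 2.87 ± 0.31. Without replicate 1 of the DDX6 arsenite input, 3344 genes passed in place of 5420.

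In DDX6 cells without arsenite 3285 genes were higher and 2819 lower in the labelled capture than in its input, but 877 and 1760 with the further threshold of 1. After DDX6 itself (4.3-fold, 4880 ± 249 against 1130 ± 36.1 CPM), the largest rise by the rule for named genes was in MARCHF7, a ubiquitin ligase (4.26-fold, 2.09 ± 0.16, 242 ± 2.58 against 56.8 ± 2.48 CPM, adjusted p = 4.25e-11, n = 2 against 2, background -0.18). Next were PNPLA8, a phospholipase (2.04 ± 0.27), the zinc finger genes ZNF627 (1.92 ± 0.32) and ZNF92 (1.85 ± 0.20), and RRM2B, a subunit of ribonucleotide reductase (1.84 ± 0.22). NORAD rose by 1.45 ± 0.20. Zinc finger genes were higher for 113 and lower for 24 of 378 (108 and 24 adjusted over the list alone, median 0.41, background -0.05, adjusted p = 0.000806, and 0.0467 with an estimated correlation). Mitosis genes were higher for 30 and lower for 2 of 41 (30 and 2 adjusted over the list alone, median 0.70, adjusted p = 1.95e-09, and 0.0884 with an estimated correlation), with the kinesin KIF18A at 1.38 ± 0.20. P-body genes were higher for 15 and lower for 3 of 41 (15 and 3 adjusted over the list alone, median 0.31, adjusted p = 0.00447, and 0.119 with an estimated correlation). Of 6 stress granule marker transcripts 3 were higher here too (3 adjusted over the list alone, median 0.54, adjusted p = 0.0279, and 0.311 with an estimated correlation).

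The same classes as under arsenite were lower in unstressed DDX6 cells. They were all 13 mitochondrial mRNAs (median -3.06, adjusted p = 0.00511 with an estimated correlation) and 72 of 75 snoRNAs and scaRNAs (75 adjusted over the list alone, median -3.50, and -0.91 after a trend with exon length was removed, background -0.56, adjusted p = 0.0467 with an estimated correlation), and 14 of 24 snRNAs (17 adjusted over the list alone, median -3.41, and -0.85 after that trend was removed, adjusted p = 0.0913 with an estimated correlation). Among longer RNAs they were 21 of 26 snoRNA host genes (22 adjusted over the list alone, median -1.50, and -0.87 without the trend, adjusted p = 0.00511 with an estimated correlation) and 60 of 80 ribosomal protein genes, with 1 higher (61 and 1 adjusted over the list alone, median -0.85, and -0.49 without the trend, background -0.26, adjusted p = 0.311 with an estimated correlation). Histones (21 of 48 lower, median -0.57, but 0.41 without the trend, background -0.45, adjusted p = 0.709 with an estimated correlation) and oxidative phosphorylation (41 of 72 lower, 2 higher, median -0.68, and -0.21 without the trend, adjusted p = 0.311 with an estimated correlation) followed. FTL fell by 1.90 ± 0.22, MALAT1 by 2.01 ± 0.23 and NEAT1 by 2.33 ± 0.25. Stress response lists did not pass, with 9 of 18 heat shock genes higher and 1 lower (adjusted p = 0.085) and 9 of 32 immediate early genes higher and 2 lower (adjusted p = 0.294). Without replicate 1 of the unstressed input, 3896 genes passed in place of 6104.

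Most genes that rose over input also rose over the no-probe capture, the control for RNA that binds without label. Both comparisons were passed by 2545 genes with TIA1, 2522 with G3BP2, 2535 with DDX6 under arsenite and 2860 with DDX6 without it, of 2789, 2986, 2935 and 3285 higher than input. Independent lists would share 661.1, 706.8, 661 and 823.1 genes. Both lists use the same labelled captures, and few genes differed between no-probe captures and inputs, so many shared genes follow from the design. In 20 simulated data sets without differences 0 such genes passed at the adjusted threshold, and between 46.55 and 52.7 on average at an unadjusted threshold. Data without differences give few adjusted calls, so the 0 does not tell what the no-probe comparison adds, nor do the numbers for independent lists. Over the no-probe captures 3404, 3399, 3234 and 3598 genes were higher and 3115, 3119, 2896 and 3312 lower. With the further threshold of 1 these were 1726, 1661, 1180 and 1320 higher and 1762, 2091, 1791 and 2191 lower, and with DDX6 under arsenite a fit to its libraries alone gave 1678 and 1765. Mitochondrial mRNAs were lower there too, at medians of -2.51 with TIA1 (adjusted p = 1.41e-24, but 0.0541 with an estimated correlation), -3.73 with G3BP2 (adjusted p = 0.00536 with an estimated correlation), -3.23 with DDX6 under arsenite and -2.77 without it. Between no-probe captures and inputs few genes passed, namely 2 higher with TIA1, 6 higher and 18 lower with G3BP2, none with DDX6 under arsenite and 1 in each direction without it.

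Across the 3 baits under arsenite 1408 genes were enriched in both comparisons with every bait, where independent sets of these sizes would share 78.9. The simulated sets shared 0, but they hold no differences and so do not weigh the overlap of sets with many calls. The count was 3537 under total counts, 885 in fits to the compared libraries alone and 230 with the further threshold of 1. Of the 1408 genes 1401 were protein-coding. DCK (gene ENSG00000156136, chromosome 4 from 70992538 to 71030914 on GRCh38) had the highest smallest rise, at 2.26 ± 0.23, 2.03 ± 0.22 and 1.84 ± 0.22 with TIA1, G3BP2 and DDX6. RRM2B followed at 1.84, 1.73 and 1.77, then NEK7, a mitotic kinase, at 2.13, 1.83 and 1.66. NBN, which senses DNA breaks, stood at 1.67, 1.59 and 1.64, ATAD2, a chromatin protein, at 1.54, 1.77 and 1.51, and ACSL4, which activates long fatty acids, at 1.63, 1.81 and 1.73. By list, the shared set held 18 of 41 mitosis genes, 7 of 41 P-body genes and 23 of 378 zinc finger genes, where it held 1408 of all 14360 tested genes, so that zinc finger genes had a smaller share than all genes. In the same way, 757 genes were lower in both comparisons with every bait, among them 57 of 75 snoRNAs and scaRNAs, 41 of 80 ribosomal protein genes and all 13 mitochondrial mRNAs. Pairs of baits shared 1660 genes (TIA1 and G3BP2, 447 expected), 1715 (TIA1 and DDX6, 449.3 expected) and 1814 (G3BP2 and DDX6, 445.2 expected), and DDX6 with and without arsenite shared 2152 (504.9 expected). These expected numbers also assume independent sets and have the same limit.

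Enriched mRNAs were poor in GC with every bait. Across 12339 protein-coding genes, enrichment and GC content had a Spearman rho of -0.66 with TIA1, -0.372 with G3BP2, -0.594 with DDX6 under arsenite and -0.572 without it. Correlations with exon length were 0.363, 0.293, 0.143 and 0.206. With GC held, the partial rank correlations with length were 0.236, 0.207, -0.04 and 0.049, so little of the length trend was left with DDX6. The no-probe captures over input went the other way, with rho for GC of 0.422, 0.464, 0.299 and 0.412. In the GC-poorest of 3 equal groups of genes, with a median GC of 40%, 49.3% of genes were higher with TIA1 and 2.41% lower, while in the richest, with a median of 59.3%, 1.58% were higher and 35.5% lower. GC content was not held in the list tests, so the list results may in part restate this trend.

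**Figure D3:**
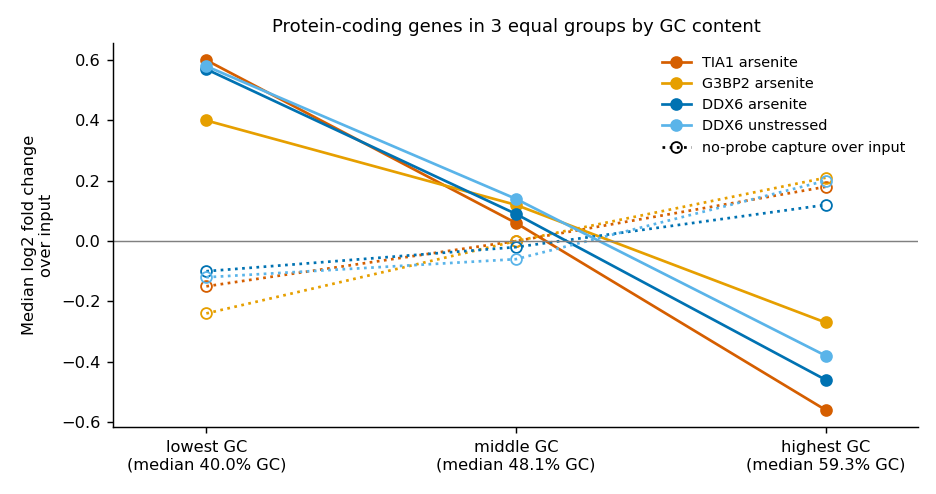
Median log2 fold change over input of protein-coding genes in 3 equal groups of 4113 by GC content, for labelled captures (solid lines) and no-probe captures (dotted lines) in the 4 combinations of cells and treatment. With TIA1 the medians were 0.60, 0.06 and -0.56 from low to high GC, and in the no-probe capture -0.15, 0 and 0.18.

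Arsenite changed few genes in how strongly DDX6 captured them. The difference of DDX6 enrichment with and without arsenite passed for 3 genes (1 higher and 2 lower, 604 at an unadjusted p under 0.05, and 3 by DESeq2). RPL22L1 (ENSG00000163584, chromosome 3 from 170864875 to 170870483) was captured over input under arsenite, at 154 against 48.0 CPM, and not without it, at 39.4 against 46.9 CPM, a difference of 1.93 ± 0.23 (adjusted p = 2.88e-05). XBP1, the transcription factor of the unfolded protein response whose mRNA is spliced at the endoplasmic reticulum, went from 210 against 73.9 CPM without arsenite to 97.3 against 97.7 CPM with it (-1.51 ± 0.28, adjusted p = 0.0366). PNRC1, a cofactor that recruits decapping proteins, changed by -1.41 ± 0.25 (adjusted p = 0.022). The calls of XBP1 and PNRC1 ended in 8 and 6 of 8 fits with 1 library left out, with adjusted p up to 0.564 (without replicate 2 of the unstressed input) and 0.349 (without replicate 1 of the arsenite input). Of 17 lists that passed camera 1 also passed with an estimated correlation, the 378 zinc finger genes, whose median was -0.22 (adjusted p = 5.53e-05, and 0.0403 with an estimated correlation), although none of them passed alone. NORAD, MALAT1 and GAPDH gave -0.57 ± 0.28, 0.01 ± 0.31 and -0.08 ± 0.27 (adjusted p = 1 each). In simulated data, 2-fold differences of this kind were found for 21 of 100 genes.

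TIA1 and G3BP2, both stress granule proteins, differed in 518 genes, with 327 captured more strongly with TIA1 and 191 with G3BP2. RNAs known to stay in the nucleus were among those with the largest differences. MIR17HG, the host transcript of the miR-17-92 cluster, was at 199 CPM in the TIA1 capture against 92.5 in its input, and at 20.9 against 119 with G3BP2, a difference of 3.61 ± 0.28 (adjusted p = 7.72e-10). MALAT1 (ENSG00000251562, chromosome 11 from 65497688 to 65506516) differed by 2.78 ± 0.31 (adjusted p = 2.23e-06), NEAT1 by 2.56 ± 0.37 (adjusted p = 8.16e-05) and KCNQ1OT1 by 1.27 ± 0.24 (adjusted p = 0.00281), although KCNQ1OT1 fell with TIA1 too (-0.97 ± 0.17). NEAT1 itself rose with TIA1 by 0.70 ± 0.25 (adjusted p = 0.0302), a call that ended by DESeq2 (adjusted p = 0.139) and in 2 of 4 fits with 1 library left out (adjusted p up to 0.244, without replicate 2 of the TIA1 input).

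**Figure D4:**
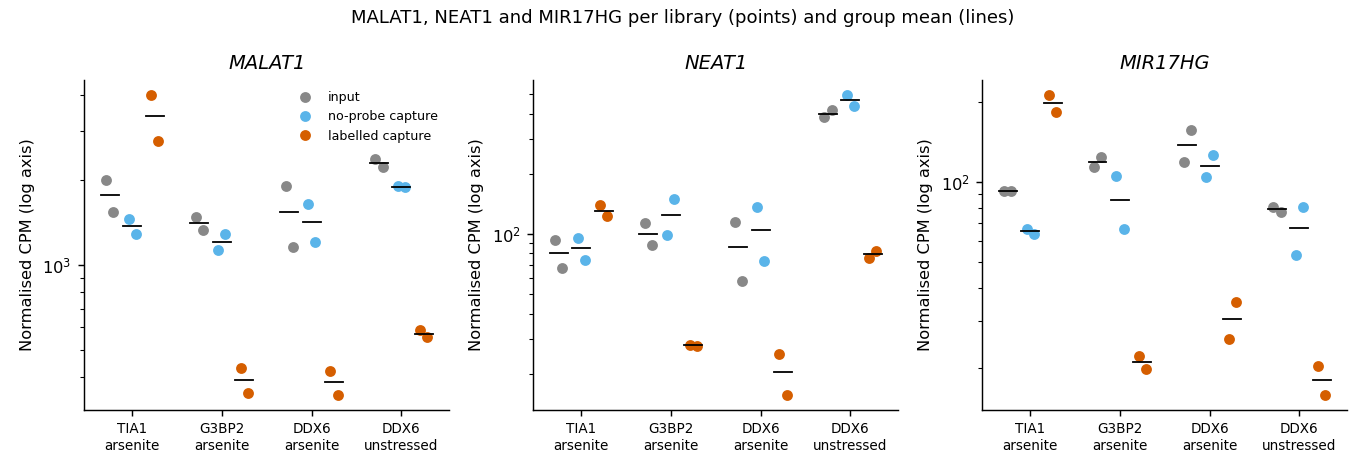
Normalised CPM (log axis) of MALAT1, NEAT1 and MIR17HG in the input, no-probe capture and labelled capture of each combination of cells and treatment; points are the 2 libraries and lines their mean. MALAT1 averaged 3390 CPM in the TIA1 labelled capture and 390, 383 and 571 CPM in those of G3BP2, DDX6 under arsenite and DDX6 without it.

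All 13 mitochondrial mRNAs were higher with TIA1 relative to G3BP2, with a median of 1.81 (adjusted p = 1.62e-29, and 0.0312 with an estimated correlation), although they fell over input with each bait. Higher too were 10 of 24 snRNAs (13 adjusted over the list alone, median 2.52, and 1.45 after a trend with exon length was removed, adjusted p = 0.281 with an estimated correlation). So were 8 of 75 snoRNAs and scaRNAs (16 adjusted over the list alone, median 1.67, and 0.63 after that trend was removed, adjusted p = 0.281 with an estimated correlation) and 6 of 26 snoRNA host genes (7 adjusted over the list alone, median 0.70, adjusted p = 0.083 with an estimated correlation). RNU5A-1 differed by 3.41 ± 0.64 and RPL36A by 2.62 ± 0.46. Of 10 lists that passed camera 3 were lower with TIA1, namely histones (median -0.47), glycolysis (-0.57) and very long cytoskeletal genes (-0.37). Of the 10 only the mitochondrial mRNAs also passed with an estimated correlation. Among further mRNAs, CHD2 differed by 1.48 ± 0.23 (adjusted p = 0.000196) and AGO3, an Argonaute protein, by 1.33 ± 0.27 (adjusted p = 0.005, and 0.0607 without replicate 1 of the TIA1 input). More strongly captured with G3BP2 was SMARCA4, a chromatin remodeller, at -1.15 ± 0.26 (adjusted p = 0.0108). Its call ended in 4 of 8 fits with 1 library left out (adjusted p up to 0.0987, without replicate 2 of the TIA1 input). NORAD at 0.54 ± 0.29 (adjusted p = 0.295) and GAPDH at -0.15 ± 0.27 (adjusted p = 0.812) showed no difference past the threshold. The count of 518 fell with most libraries left out, to 127 without replicate 1 and 307 without replicate 2 of the TIA1 labelled capture, and 185 and 153 without those of its input. It was 168 without replicate 2 of the G3BP2 labelled capture, and 131 and 147 without replicates 1 and 2 of its input. The split between the TIA1 and the G3BP2 side varied too. It was 284 and 46 under total counts, 561 and 482 in a fit to the compared libraries alone, and 517 and 513 with the no-probe captures as reference. The split turned to 624 and 654 with replicate number as a block, although pairs were not shown for all libraries. With 1 library left out it ranged from 192 and 115 (replicate 2 of the TIA1 labelled capture) to 112 and 19 (replicate 1 of the G3BP2 input) among the fits named here.

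DDX6 compared with TIA1, both under arsenite, gave 121 genes captured more strongly with DDX6 and 217 with TIA1. RPL22L1 was captured more strongly with DDX6 here as well (2.39 ± 0.24, adjusted p = 2.07e-07). SLIRP, an RNA-binding protein of mitochondria (1.88 ± 0.33, adjusted p = 0.00118), was at 39.6 against 36.7 CPM with DDX6 and 11.2 against 38.6 CPM with TIA1. EEF1B2, a translation elongation factor, had a larger estimate (3.03 ± 0.78, adjusted p = 0.0324) with inputs that disagree (61 and 19 counts with TIA1). That call ended in 6 of 8 fits with 1 library left out (adjusted p up to 0.297, without replicate 1 of the TIA1 input). Nuclear RNAs were lower with DDX6, with MALAT1 at -2.93 ± 0.31 (adjusted p = 6.42e-07) and NEAT1 at -2.75 ± 0.38. The mRNA of CHD2 was lower too, at -1.53 ± 0.23. Lower as well were 8 of 24 snRNAs (10 adjusted over the list alone, median -1.84, and -0.83 after a trend with exon length was removed, adjusted p = 0.194 with an estimated correlation), with RNU4-1 at -3.66 ± 0.64. Ribosomal protein genes were higher for 8 and lower for 1 of 80 (38 and 1 adjusted over the list alone, median 0.60, adjusted p = 0.212 with an estimated correlation). Histones were higher for 4 of 48 (28 higher and 1 lower adjusted over the list alone, median 0.92, adjusted p = 0.194 with an estimated correlation) and oxidative phosphorylation for 6 of 72 (17 adjusted over the list alone, median 0.52, adjusted p = 0.194 with an estimated correlation). Of 13 mitochondrial mRNAs 5 were lower (13 adjusted over the list alone, median -1.05, adjusted p = 0.127 with an estimated correlation). The total of 338 was 144 without replicate 2 of the TIA1 labelled capture, and 39 higher and 84 lower with DDX6 when its replicate 1 was left out, 96 and 107 without those of its input, 156 without replicate 2 of the DDX6 labelled capture and 114 without replicate 1 of the DDX6 input. A fit to the compared libraries alone gave 11 genes higher and 62 lower with DDX6, and the no-probe captures as reference gave 467 and 562. The balance turned to 511 and 487 with replicate number as a block, although pairs were not shown for all libraries.

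DDX6 compared with G3BP2, both under arsenite, gave 7 genes captured more strongly with DDX6 and none with G3BP2 (1580 genes at an unadjusted p under 0.05, and by DESeq2 42 with DDX6 and 39 with G3BP2). Replicate number as a block gave 126 with DDX6 and 102 with G3BP2, although pairs were not shown for all libraries. RPL22L1 was at 154 against 48.0 CPM with DDX6 and 37.7 against 69.1 CPM with G3BP2 (2.55 ± 0.23, adjusted p = 3.57e-08). CKS2, a subunit of cell cycle kinases, was at 119 against 62.2 CPM and 39.3 against 83.8 CPM (2.02 ± 0.23, adjusted p = 2.84e-06). These are also the 2 genes that were higher with DDX6 than with both other baits. Both comparisons use the same DDX6 libraries, and 20 simulated data sets without differences gave 0 such genes at the adjusted threshold and 70.65 on average at an unadjusted threshold. Data without differences give few adjusted calls, so the 0 does not weigh this overlap. The tubulin gene TUBE1 (1.50 ± 0.28), ID2 (1.47 ± 0.25), TM2D3 (1.35 ± 0.25) and the centromere gene CENPK (1.31 ± 0.27) also passed. Their calls ended in 5, 2, 6 and 8 of 8 fits with 1 library left out (adjusted p up to 0.204, 0.121, 0.169 and 0.293, without replicate 2 of the G3BP2 input, or replicate 1 of the DDX6 input for TM2D3). The count of 7 was 2 without replicate 2 of the G3BP2 labelled capture, and 3 and 2 without replicates 1 and 2 of its input. It was 15 without replicate 1 of the DDX6 labelled capture, and 3 and 12 without replicates 1 and 2 of the DDX6 input.

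In the input RNA of the DDX6 cells arsenite raised 52 genes and lowered 113. Immediate early genes, which cells switch on within minutes of a stimulus, led the rise. FOS, which held 5 and 2 counts without arsenite, went from 1.03 ± 0.543 to 97.4 ± 15.4 CPM (6.49 ± 0.45, adjusted p = 1.7e-11, n = 2 against 2). EGR1 went from 5.28 ± 2.92 to 246 ± 39.9 CPM (5.50 ± 0.30, adjusted p = 2.06e-14), FOSB from 7.98 to 58.1 CPM (2.83 ± 0.33) and the phosphatase gene DUSP1 from 27.3 to 86.9 CPM (1.67 ± 0.21, adjusted p = 9.28e-06). Of 32 immediate early genes 12 rose and none fell (18 and 2 adjusted over the list alone, median 0.98, adjusted p = 7.8e-28, and 0.0005 with an estimated correlation). Heat shock genes rose for 2 of 18 tested (9 adjusted over the list alone, median 0.48, adjusted p = 9.2e-08, and 0.197 with an estimated correlation). HSPA1A and HSPA1B, which belong to this list, were not among the tested genes, so their response is not known here. The cochaperone DNAJB1 was at 1.44 ± 0.27 (adjusted p = 0.00505, up to 0.458 in 4 fits with 1 library left out, 2 of which ended the call, without replicate 2 of the arsenite input). Of 18 NRF2 targets none passed alone, though the list had a median of 0.24 (adjusted p = 0.012, and 0.299 with an estimated correlation), and HMOX1, heme oxygenase 1, was at 0.26 ± 0.20 (adjusted p = 0.54). ATF4 targets rose for 3 and fell for 1 of 26 (4 and 1 adjusted over the list alone, median 0.13, but -0.08 under total counts, adjusted p = 0.012, and 0.492 with an estimated correlation).

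Several long transcripts were lower in the arsenite input, and across 12339 protein-coding genes the change had a Spearman rho of -0.321 with exon length. NEAT1 fell from 399 ± 22.6 to 86.7 ± 40.5 CPM (-2.21 ± 0.25, adjusted p = 2.76e-06) and PLEC, the cytoskeletal linker plectin, from 149 ± 3.35 to 55.2 ± 5.61 CPM (-1.44 ± 0.18, adjusted p = 9.28e-06). Chromatin regulators were lower for 8 of 51 (22 lower and 1 higher adjusted over the list alone, median -0.34, and -0.13 after that trend with length was removed, adjusted p = 7.26e-14, and 0.0877 with an estimated correlation). Very long cytoskeletal genes were lower for 6 of 40 (15 adjusted over the list alone, median -0.40, and -0.08 after its removal, adjusted p = 5.52e-14, and 0.142 with an estimated correlation). EP400, a remodeller, was at -1.10 ± 0.20 (adjusted p = 0.0029, and 0.165 without replicate 2 of the arsenite input). AHNAK was at -1.18 ± 0.31 (adjusted p = 0.0483, but 0.208 by DESeq2 and up to 0.825 with 1 library left out, without replicate 2 of the arsenite input, with the call ended in 3 of 4). No ribosomal protein gene passed alone, though the list had a median of 0.31 (adjusted p = 7.54e-11, and 0.368 with an estimated correlation). The count of 165 was 20 without replicate 1 of the unstressed input (10 higher and 10 lower), 36 without its replicate 2 (14 and 22), 419 without replicate 1 of the arsenite input (216 and 203) and 20 without its replicate 2 (13 and 7). Under total counts 23 were higher and 261 lower, so the balance of 52 and 113 depends on the libraries and the scaling.

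**Figure D5:**
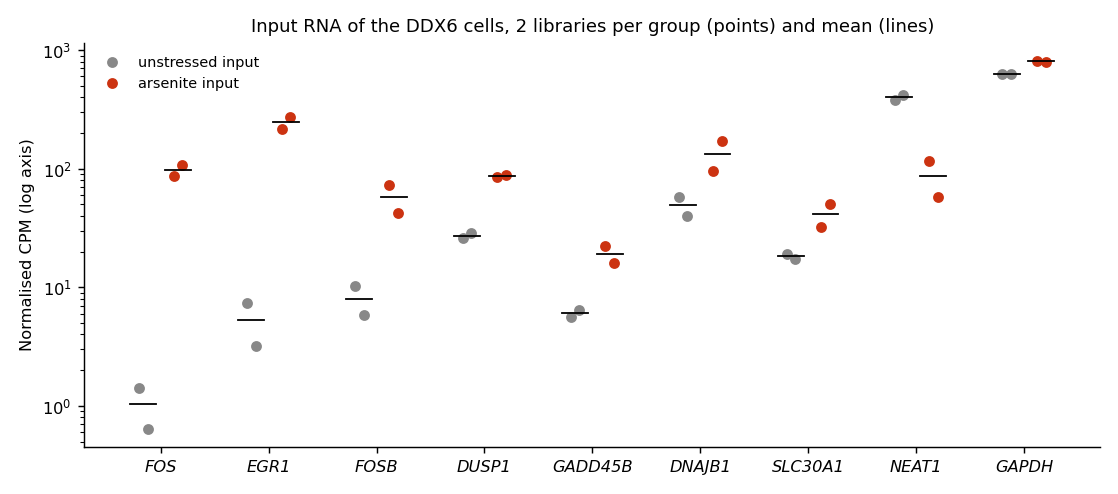
Normalised CPM (log axis) of 9 genes in the inputs of DDX6 cells without and with arsenite; points are the 2 libraries of each group and lines their mean. EGR1 averaged 5.28 CPM without and 246 CPM with arsenite, and NEAT1 399 and 86.7 CPM.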

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

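The tests of the differences between baits and between treatments were planned, while the tests that weigh explanations were chosen only after the results were seen, except the scaling test. Each result here is a difference of enrichment between cells or treatments by edgeR's quasi-likelihood test, or a list that passed camera in such a comparison with an estimated correlation as well.

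For DDX6 with against without arsenite 3 genes differed, RPL22L1 by 1.93 (adjusted p = 2.88e-05, the call kept in each of 8 fits with 1 library left out), XBP1 by -1.51 and PNRC1 by -1.41. The calls of XBP1 and PNRC1 ended in 8 and 6 of 8 such fits (adjusted p up to 0.564 without replicate 2 of the unstressed input and 0.349 without replicate 1 of the arsenite input). The zinc finger genes as a list differed by a median of -0.22. Between TIA1 and G3BP2 518 genes differed. The largest by the rule for named genes were RNA5SP149 at 4.97, RNA5S9 at 3.79, MIR17HG at 3.61, RNU5A-1 at 3.41, RNU5D-1 at 3.15 and RNU4-1 at 3.12 on the TIA1 side. They were MIR3687-2 at -3.48, MIR3648-2 at -3.05, PDXP at -2.16 and TSR3 at -1.67 on the G3BP2 side. The G3BP2 captures held 0 and 2 counts of RNA5SP149, so its fitted value depends on the prior count and is no measured fold. Its call ended in 6 of 8 fits with 1 library left out (adjusted p up to 0.126). For PDXP, TSR3, MIR3687-2 and MIR3648-2 the call ended in 5, 4, 3 and 1 of 8 such fits, with adjusted p up to 0.231, 0.0754, 0.0762 and 0.054. The first was without replicate 2 of the TIA1 input and the others without replicate 2 of the G3BP2 labelled capture. The 5S, U snRNA and MIR3687 and MIR3648 genes have near-identical copies, so counts of single copies are uncertain.

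Between DDX6 and TIA1 338 genes differed, led by EEF1B2 at 3.03, RPL22L1 at 2.39, SLIRP at 1.88, RPS3AP26 at 1.73, RF01518 at 1.57 and EEF1B2P3 at 1.51 on the DDX6 side. On the TIA1 side were RNVU1-31 at -3.88, RNU4-1 at -3.66, RNVU1-7 at -3.65 and RNU5D-1 at -3.50. The calls of EEF1B2, RPS3AP26 and RF01518 ended in 6 of 8 fits with 1 library left out, with adjusted p up to 0.297, 0.184 and 0.138 (without replicate 1 of the TIA1 input, replicate 1 of the DDX6 input and replicate 2 of the TIA1 input). That of RNU5D-1 ended in 2 of 8 (up to 0.0728, without replicate 2 of the DDX6 labelled capture). RPS3AP26 and EEF1B2P3 are pseudogenes, and reads of their parent genes were not told apart from theirs. Between DDX6 and G3BP2 7 genes differed, among them RPL22L1 at 2.55, CKS2 at 2.02, TUBE1 at 1.50, ID2 at 1.47, TM2D3 at 1.35 and CENPK at 1.31. The calls of TUBE1, ID2 and TM2D3 ended in some of the fits with 1 library left out, and that of CENPK in all of them.

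The 13 mitochondrial mRNAs were higher with TIA1 than with G3BP2 by a median of 1.81, and nuclear RNAs such as MALAT1 by 2.78 ± 0.31. Scaling does not account for the mitochondrial part, since its median was 1.92 under total counts. Unlabelled input RNA carried through the TIA1 capture would set a lower limit for every RNA, yet 31 genes outside the mitochondrial genome lay below the median of the mitochondrial mRNAs by more than 2 SE, 28 of them with exons under 400 nt, which the no-probe capture held at a median of 0.05 relative to input. Carry-over is thus not the only source of the mitochondrial reads, but a limit below their median could still supply part of them. Of other lists that fell with both baits, snRNAs (2.52), snoRNAs and scaRNAs (1.67), cytoplasmic small RNAs (1.56) and snoRNA host genes (0.70) had higher medians with TIA1. Ribosomal protein (-0.05), histone (-0.47), oxidative phosphorylation (-0.06) and cytoskeleton genes (-0.12) did not, so partial carry-over stays open. In the nuclear part, carry-over cannot raise MALAT1 by 0.93 ± 0.22 over input (0.65 and no longer past the threshold without replicate 1 of the TIA1 labelled capture, adjusted p = 0.0583), and the inputs of the lines differed by 0.34 ± 0.22 in MALAT1 and -0.33 ± 0.26 in NEAT1, far less than the enrichments, although by -0.65 ± 0.17 in KCNQ1OT1 (adjusted p = 0.0258), a large part of its enrichment difference of 1.27 but not all, with 0.61 ± 0.17 between its captures. Labelling of nuclear RNA by the TIA1 bait stays open, as does a difference between the lines, since 2 of 3 nuclear-retained RNAs (MALAT1 and NEAT1) were above both input and no-probe captures, the call of NEAT1 ended by DESeq2 (adjusted p = 0.139) and in 2 of 4 fits with 1 library left out (adjusted p up to 0.244, without replicate 2 of the TIA1 input), and KCNQ1OT1 fell (-0.97 ± 0.17).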

How the results depend on the processing

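The no-probe captures as reference were an alternative chosen only after the results were seen, and the others were planned. Of 172 alternative values of the counts and list tests, 127 were within 1.5 times of the reported value and 45 moved. The cause of a move was not tested. These labels compare totals only, so a changed balance of higher and lower genes does not enter them. Under total counts the differences gave 1 gene for arsenite with DDX6, 330 (284 higher and 46 lower) for TIA1 minus G3BP2 and 2 for DDX6 minus G3BP2, the inputs 284 (23 higher and 261 lower), the sets enriched in both comparisons 6060, 4319, 5040 and 4635 (TIA1, G3BP2, DDX6 with and without arsenite), and the shared set 3537. For DDX6 minus G3BP2, leaving out mitochondrial and rRNA genes gave 16 (11 higher and 5 lower with DDX6), no filter 55 (23 and 32), a filter at 50 counts 19 (12 and 7) and DESeq2 81 (42 and 39). No filter gave 17 for the arsenite difference. Fits to the compared libraries alone gave 2700 for enrichment and 3443 for probe dependence with DDX6 under arsenite, 1133 for both, and 885 for the shared set. They gave 1 for the arsenite difference, 1043, 73 and 3 for TIA1 minus G3BP2, DDX6 minus TIA1 and DDX6 minus G3BP2, and 42 for the inputs. With replicate number as a block the differences gave 6, 1278 (624 higher and 654 lower with TIA1), 998 (511 higher and 487 lower with DDX6) and 228 (126 higher and 102 lower with DDX6). Over 9475 genes with a mean of at least 10 CPM, the replicate differences of pairs of library kinds correlated with r of 0.61, 0.36 and 0.26 in DDX6 cells under arsenite, as paired libraries would, but with r from -0.06 to 0.29 in the other 3 combinations, so pairs were not shown for all libraries of any difference. A further threshold of 1 on the log2 scale, which by construction keeps fewer genes, gave 2189, 2543, 2320 and 2637 for enrichment, 3488, 3752, 2971 and 3511 for probe dependence, 913, 784, 612 and 647 for both, 230 for the shared set and 96 for the inputs. No-probe captures as reference gave 1030 (517 higher and 513 lower with TIA1), 1029 and 4 for the differences between baits. With an estimated correlation 21 of 180 list calls held. After a loess trend with exon length was removed, 169 of the 180 list medians stayed on the side of the call and 11 did not. With each library left out in turn the enrichments ranged from 3267 to 4284, 3633 to 4980, 3344 to 4731 and 3896 to 4558. The arsenite difference ranged from 1 to 3, TIA1 minus G3BP2 from 127 to 468, DDX6 minus TIA1 from 96 to 398, DDX6 minus G3BP2 from 2 to 15 and the inputs from 20 to 419, and a fit with fewer libraries has less power. Probe dependence ranged from 4687 to 5725, 4666 to 6163, 4521 to 5582 and 5188 to 5576, and the shared set from 1124 to 1583. Of 829 named gene results, DESeq2 ended 16 calls and added 27, the block added 56, and among 4784 values with a library left out 328 calls ended, 26 were added and 0 reversed. Depth was not varied, so its share in the limits below is not known. At these depths with 2 libraries per group, of 100 simulated 2-fold changes 21 were found for the arsenite difference of DDX6 enrichment, 59 for enrichment with TIA1 and 44 for the inputs. Of 14360 simulated genes 14120 were unchanged, while 5138 passed for the real enrichment with TIA1, so the 59 need not hold there.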

Other observations

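The descriptions below and the tests of length, of guanine share in 2 forms and of the need for arsenite were chosen only after the results were seen, while the tests of GC content in the no-probe captures and of a shared trend were written before.

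The 52 genes raised by arsenite in the DDX6 input had a median enrichment of -0.18 with TIA1, where 8 were higher and 12 lower than input, -0.33 with G3BP2 (3 higher, 19 lower) and -0.44 with DDX6 under arsenite (5 higher, 20 lower), against medians of 0.02, -0.01 and -0.02 for all tested genes and -0.06, -0.13 and -0.14 for the 52 in the no-probe captures. FOSB, an immediate early gene, fell with G3BP2 by 2.31 ± 0.27 and with DDX6 under arsenite by 2.87 ± 0.31. The DDX6 inputs that define these genes are also the reference of its captures, which by construction lowers their DDX6 enrichment under arsenite and raises it without (0.25, with 15 higher and 8 lower), and those of the other 2 lines are not shared. The 52 genes had a median GC of 51.8% and a median exon length of 2829 nt, against 48% and 3533 nt for all tested genes. Enrichment of mRNAs fell with GC and rose with length with every bait. With GC held, the length trend remained with TIA1 and G3BP2 (partial rank correlations of 0.236 and 0.207). It was near 0 with DDX6 (-0.04 with arsenite and 0.049 without it). Neither GC nor length was held for the 52 genes, so these trends cannot be told apart from an effect of induction. No test of this set against the rest was made.

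By type of gene, the RNAs captured more strongly with TIA1 than with G3BP2 included 23 of 334 tested long intergenic RNAs with 1 in the other direction, 23 of 479 antisense genes with none in the other, and 13 of 32 snRNA genes with none in the other, against 214 higher and 185 lower of 12339 protein-coding genes. The medians of these types were 0.75, 0.80, 2.45 and -0.05. Counts of antisense genes are uncertain because the strand setting is not stated.

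Messenger RNAs poor in GC were enriched with every bait. A bias of the capture and library steps without label would give the no-probe captures the same trend, but their rho with GC was at least 0.299, the opposite sign. Length, as measured on the longest transcript, does not account for it, with a partial rank correlation with GC given length of -0.313 or lower in each capture. More label on RNAs with more guanines would by its sign oppose the trend if label acted only through stronger capture, which was not tested. Whether such labelling acts beside the trend stays open. The guanine share went with the cytosine share (rho of 0.836), so that its own rho of -0.282 or lower largely restates the trend. Its partial rank correlation given the cytosine share went from -0.13 with TIA1 to 0.131 with G3BP2. Also open is a property that goes with low GC, such as weak folding, or where such mRNAs lie in the cell, neither of which was tested here.

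Of the 1408 genes shared by the 3 baits under arsenite, 94.2% were also enriched in both comparisons in unstressed DDX6 cells, against 19.9% of all tested genes, and so were 86.7% of the 1660 shared by TIA1 and G3BP2, a set not chosen with DDX6. An enrichment that needs arsenite would leave most of them out there. A shared trend with GC content and length does not account for all of it, since the enrichments with TIA1 and with unstressed DDX6 correlated across mRNAs with r of 0.61, and 0.41 after trends with both were taken out. The choice of genes that passed with 3 baits favours well-measured genes, and whether the shared part comes from RNAs that lie in granules or from RNAs that any cytoplasmic bait may label stays open, since no bait outside granules was measured.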
